A study of Homo sapiens with 40 samples.

How the data were processed

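RNA-seq covered HEK293T cells in 3 groups of 2 libraries, the wild type (WT) and the RNASEH2A knockout clones T3-8 and T3-17, and DNA-seq covered genomic DNA of CD4+ T cells fragmented in 4 ways with 1 library each. Groups were taken from the labels and never from the values. The WT titles say HEK293 where the cell line label says HEK293T, and the labels do not say that WT is the parent of the clones. RNA was cleaned on columns with a DNase step, selected for poly(A) and made into strand-specific libraries sequenced as read pairs, per the labels' protocols. Of the 40 samples in the series 10 were used, and the 26 ribose-seq and 4 bisulfite samples were not analysed here. The DNA came from a human donor, so only comparisons between methods and summary evenness are given for it.

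The RNA values are TPM (from the values, reads divided by gene length and scaled to the same total in each library) as deposited by the authors, with gene coordinates and merged exon lengths per the file headers, which follow the layout of a featureCounts table. The submitters' processing notes name featureCounts, Bowtie2, Bismark and the build GRCh38 without a version. The RNA aligner, the annotation release and the strand setting are not given in the sources used here. Multiplying each TPM by gene length gave whole multiples of 1 step per library for 100% of values at a tolerance of 0.001, which returned the number of reads. The deposited DNA values are coverage signal per 500 kb bin and strand, per the file headers. They were read as depth summed over the bases of a bin, from their size, since the headers do not define them.

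The table held 18656 genes, of which 18626 (99.8%) had a symbol, and only the 22 autosomes. Genes at a TPM of 1 or more in at least 2 libraries were kept, 13790 in all. limma was run on log2(TPM + 1) with 1 mean per group, an intensity trend in the prior, 3 residual and 4.49 prior degrees of freedom. Benjamini-Hochberg adjustment covered all kept genes, with calls at an adjusted p under 0.05. Fold changes on this scale understate changes of genes at low TPM. A read in a gene of 1 kb stood for 0.1 to 0.125 TPM, so values below 1 TPM rest on few reads.

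Comparisons were each clone with WT, the calls shared by both clones, and T3-17 with T3-8. Because the clones share the WT libraries, 100 draws of unchanged clones were simulated for the shared calls and for the correlation of fold changes. In each draw the WT values were simulated too and were shared by both clones. The 33 gene lists were fixed before the data were examined and tested with camera of limma at a preset correlation of 0.01 and with an estimated correlation, with fry beside it, over lists with at least 5 kept genes. With an estimated correlation camera also takes its reference from the 3 residual degrees of freedom. Members were counted over all genes and adjusted over the list alone. Chromosomes were tested as sets in the same way, and windows of 20 Mb with at least 20 genes were summarised.

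Named genes followed a rule set before the data were examined. It took RNASEH2A, RNASEH2B, RNASEH2C and RNASEH1, the 10 largest rises and 10 largest falls shared by the clones, the 4 of each in a clone alone, the 5 of each between the clones, and up to 4 members of a list by adjusted p. It required both libraries of a group to lie beyond both of the other and a mean of 5 TPM or more in the higher group. PCDHGC3 is among the listed genes, and the check for reads shared by the protocadherins was chosen after the values were seen. Overlap of annotated exons was screened for all kept genes: 2684 overlap another gene, 1474 over more than 20% and 866 over more than 50% of their exon length.

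For DNA, strands were summed and each library was scaled by its autosomal total. Of 5760 bins 211 had no signal in any of the 4 libraries. Ratios to dsF used bins at or above 0.5 times the dsF median. Intervals came from 1000 bootstrap draws over bins or from the exact binomial distribution. No test between methods was made with 1 library each.

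Alternatives set before the data were examined were pseudocounts of 0.1 and 5, no abundance filter (17243 genes) or a filter at 5 TPM (12005 genes), median-ratio scaling, quantile normalization of genes, a replicate block, no intensity trend, fits of 1 clone with WT, leaving out each library, an estimated correlation, and for DNA other bin filters and scaling. Cyclic loess, voom on recovered reads, quantile normalization of lists, chromosomes and the correlation, and omission of the protocadherin list were chosen after seeing the data.

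The scripts' steps were tested on simulated data. For T3-8 against WT with 13790 genes, 49 of 67 genes changed 1.5-fold were recovered (73.1%), 61 of 67 at 2-fold (91%) and 65 of 66 at 4-fold (98.5%). Of 13590 unchanged genes 26 were called, a larger part of all calls than the threshold aims at, and 2 of 13790 for T3-17 against WT. The list and chromosome tests each recovered the 1 shifted set and passed none of the 29 and 21 others. The DNA step found 40 of 40 lowered bins and no others. Tools were R 4.3.3, limma 3.58.1, data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.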

Results

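The RNA-seq data came from cells labelled HEK293T, a human embryonic kidney line: wild-type cells and knockout clones in which RNASEH2A was targeted. The labels do not say that the wild-type cells, titled HEK293, were the parent of the clones. RNASEH2A encodes the catalytic subunit of RNase H2, the enzyme that starts the removal of ribonucleotides built into DNA. There were 6 libraries of poly(A)-selected RNA, 2 from wild-type (WT) cells, 2 from the knockout clone T3-8 and 2 from the knockout clone T3-17. Reads recovered from the TPM values came to 22528583 and 25455283 in the WT libraries, 24464320 and 25634455 in T3-8, and 27944927 and 27400922 in T3-17. Of the 18656 genes in the table, all on the 22 autosomes, 13790 passed the abundance filter and were tested. The labels do not say that the 2 replicates of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The DNA data were binned coverage of genomic DNA from blood CD4+ T cells, cut by 4 fragmentation methods with 1 library each. A further 30 samples of the series, 26 of ribose-seq and 4 of bisulfite sequencing, were not analysed here.

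RNASEH2A transcripts were lower in both clones than in WT and remained detectable in each library. The gene (ENSG00000104889; GRCh38 chromosome 19, 12806555 to 12815201, 8 exon blocks) had 85.3 and 93.0 TPM in the WT libraries, 23.9 and 24.8 TPM in T3-8, and 34.9 and 47.3 TPM in T3-17. The mean was 89.2 ± 5.47 TPM in WT (SD, n = 2), 24.3 ± 0.592 in T3-8 and 41.1 ± 8.77 in T3-17. On the log2(TPM + 1) scale it fell by 1.83 in T3-8 (SE 0.142; limma, Benjamini-Hochberg adjusted p = 0.000309) and by 1.11 in T3-17 (SE 0.142; adjusted p = 0.00111). The labels of all 4 clone libraries thus go with a lower level of the targeted transcript. A gene-level TPM does not show whether the remaining transcripts carry the edited exon.

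The partner subunits did not move together. RNASEH2C, which encodes a structural subunit of the enzyme, rose from 148 ± 5.27 TPM in WT to 201 ± 4.06 in T3-8 (log2 fold change 0.44, adjusted p = 0.00523) and was lower in T3-17, at 112 ± 6.96 TPM (log2 fold change -0.40, limma adjusted p = 0.00675). Of its exon length 28.7% overlaps KAT5, and both calls are uncertain. RNASEH2C lies on chromosome 11, whose genes had a median of -0.40 in T3-17 relative to all genes. The fold change of the gene is not relative to all genes, whose median was 0.15 in T3-17, so these values differ in scale. The fall of RNASEH2C in T3-17 may in part be that of the chromosome. The rise in T3-8 no longer passed with median-ratio scaling (limma adjusted p = 0.0685), without WT replicate 2 (0.0623) or without T3-8 replicate 1 (0.0608), nor the fall in T3-17 without WT replicate 1 (0.0768). RNASEH2B, the other structural subunit, had 12.1 ± 3.81 TPM in WT, 17.9 ± 4.51 in T3-8 and 15.9 ± 4.58 in T3-17 and passed in neither clone (limma adjusted p = 0.147 and 0.299). RNASEH1, which encodes the other nuclear enzyme that cuts RNA:DNA hybrids, had 64.8 ± 1.06, 77.6 ± 1.02 and 58.3 ± 9.17 TPM in the same order. With TPM as deposited and all 6 libraries it passed in neither clone (limma adjusted p = 0.106 and 0.292), and with median-ratio scaling it passed in T3-17 (log2 fold change -0.31, adjusted p = 0.0326). Without T3-17 replicate 1 it passed in T3-8 (0.00317) and in T3-17 (0.00339), and without T3-17 replicate 2 it passed in T3-8 (0.00295).

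**Figure D1:**
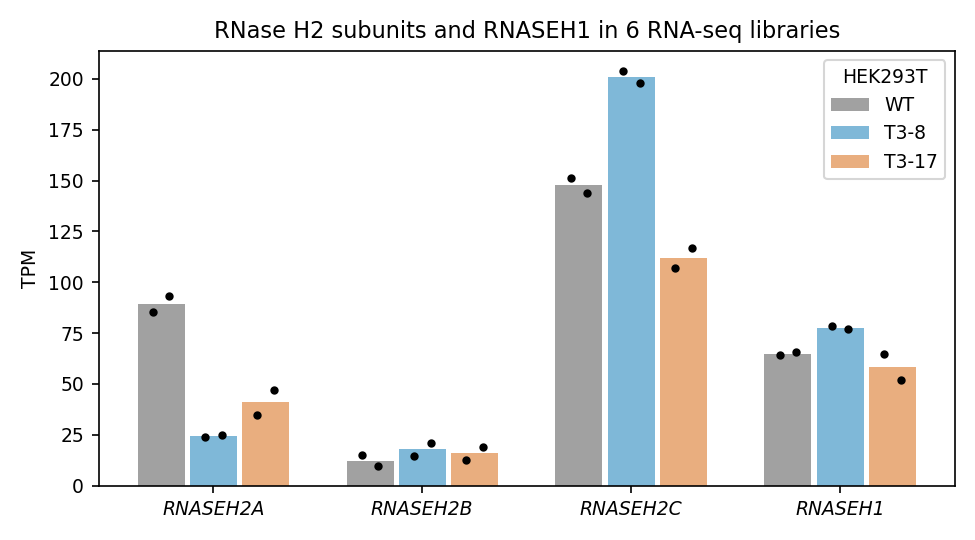
Transcript levels (TPM, linear axis from 0) of the RNase H2 subunit genes RNASEH2A, RNASEH2B and RNASEH2C and of RNASEH1 in WT, T3-8 and T3-17; bars are means of 2 libraries and points are the libraries. RNASEH2A means were 89.2 TPM in WT, 24.3 in T3-8 and 41.1 in T3-17.

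Genes that differed from WT in both knockout clones were compared first. PPP2R2C, a regulatory subunit of a serine/threonine phosphatase (chromosome 4, 6320580 to 6472614), rose from 1.97 ± 0.484 TPM in WT to 19.2 ± 0.715 in T3-8 and 22.3 ± 0.943 in T3-17 (SD, n = 2; log2 fold changes 2.77 and 2.98, SE 0.145). KIF1A, a kinesin motor of axonal transport (chromosome 2, 240713768 to 240820308), rose from 14.8 ± 0.718 to 74.6 ± 0.162 and 90.7 ± 4.91 TPM, and the surface glycoprotein gene CD24 from 4.73 ± 0.482 to 25.8 ± 2.61 and 51.6 ± 8.21 TPM. HES5, a transcriptional repressor downstream of Notch, went from 2.07 ± 0.262 TPM to 16.1 ± 5.47 and 16.1 ± 4.66. TNFRSF10D, a decoy receptor for the death ligand TRAIL (chromosome 8, 23135587 to 23164027), fell from 45.02 ± 1.69 TPM to 5.36 ± 0.0877 in T3-8 and 7.88 ± 0.286 in T3-17 (log2 fold changes -2.86 and -2.37, SE 0.111). The transferrin receptor gene TFRC (chromosome 3, 196049283 to 196082090) fell from 412.5 ± 8.42 TPM to 159 ± 1.57 and 123.9 ± 14.1.

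The other genes with the largest shared rises were PPP1R1A, FAXDC2, the connexin gene GJB2, the neuropeptide gene NMU, the sterol transporter gene ABCG1 and the endoplasmic reticulum aminopeptidase gene ERAP2. Their smaller log2 fold change of the 2 clones lay between 1.89 for ERAP2 and 2.50 for PPP1R1A. SNAI2, a repressor of epithelial genes, fell from 134 ± 5.14 TPM to 14.3 ± 0.207 in T3-8 and 59.2 ± 20.2 in T3-17, and the glial glutamate transporter gene SLC1A3 from 122.4 ± 3.68 to 53.8 ± 0.0741 and 40.2 ± 10.5. DDN, RAB39A, IDI1, PAK1IP1, GPATCH4 and RNASEH2A itself made up the rest of the 10 largest shared falls. For the 20 genes the limma adjusted p lay between 2.83e-05, for KIF1A in T3-17, and 0.00376, for DDN in T3-8.

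Across all tested genes, 4390 were called higher and 1258 lower in T3-8 than in WT, and 4198 higher and 1732 lower in T3-17 (limma, Benjamini-Hochberg adjusted p under 0.05). Of these, 2482 were higher and 585 lower in both clones. Independent lists of these sizes would share 1336 higher and 158 lower genes. In 100 simulations of unchanged clones that share simulated WT libraries, a mean of 0.02 calls and at most 1 were shared. No gene was changed in these draws, so few calls could arise. They do not show how many calls clones that each differ from WT would share. At a fold change of 2 or more, 359 genes were higher and 11 lower in both clones. The WT libraries were not split between the clones, since each part would hold 1 library, so part of the excess may come from the shared controls.

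The share of calls that were higher depended on the scaling. The median log2 fold change of all tested genes was 0.19 in T3-8 and 0.15 in T3-17, and gene groups and chromosomes are reported relative to this shift. With TPM as deposited 77.7% of the T3-8 calls, 70.8% of the T3-17 calls and 80.9% of the shared calls were higher. With median-ratio scaling these shares were 51.2%, 50.3% and 52%, with quantile normalization 49.8%, 47.6% and 51.6%, and with cyclic loess normalization, chosen after seeing the data, 51.8%, 51.9% and 56.1%. Of the 3067 shared calls, 69.8% were called in the same direction with median-ratio scaling, 46.3% with quantile normalization and 51.7% with cyclic loess.

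Single libraries also moved the counts. The spread is shared by all 3 groups, and the T3-17 replicates were less alike than the others. The cause of each move was not tested. For the 5648 calls in T3-8, leaving out a WT library gave 2780 (replicate 1) or 2740 (replicate 2), leaving out a T3-8 library gave 2461 or 2471, and leaving out a T3-17 library gave 8572 or 8583. The 5930 calls in T3-17 became 3272 or 3155 without a WT library. The 3067 shared calls became 1363 or 1329 without a WT library, 1465 or 1441 without a T3-8 library, and 4984 without T3-17 replicate 2.

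Some of the largest changes were called in 1 clone and not in the other, and the difference between clones was tested directly. NLRP1, an inflammasome sensor gene (chromosome 17, 5514117 to 5584509), rose in T3-8 from 0.371 ± 0.0864 to 14.4 ± 0.0277 TPM and had 0.224 ± 0.135 TPM in T3-17 (T3-17 against T3-8, log2 fold change -3.65, SE 0.167; limma adjusted p = 3.75e-05). ONECUT3, KISS1R and DCT also rose in T3-8, by 2.65 to 2.89 on the log2 scale, and were lower in T3-17 than in T3-8 by limma (adjusted p = 0.000237, 0.00106 and 0.000235). LTBR, the lymphotoxin beta receptor gene, fell in T3-8 from 7.97 ± 0.908 to 0.848 ± 0.603 TPM and had 7.66 ± 0.213 TPM in T3-17 (between clones 2.27; limma adjusted p = 0.000811). TGFBI, BCL6B and HBA1 also fell in T3-8, with differences between clones of 2.21, 1.64 and 1.55. The HBA1 call was lost without WT replicate 1 (limma adjusted p = 0.0602).

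In T3-17, DKK4, which encodes a secreted Wnt inhibitor, was listed at 0 in the 4 WT and T3-8 libraries and had 7.34 ± 0.307 TPM. SPINT2, a serine protease inhibitor gene (chromosome 19, 38264572 to 38292615), rose from 36.3 ± 0.98 TPM in WT to 229.4 ± 60.2 in T3-17, against 38.6 ± 2.38 in T3-8 (between clones 2.52; limma adjusted p = 0.00016). GNG2 and RASAL1 rose by 2.39 and 2.21 and were higher in T3-17 than in T3-8 by 1.68 and 2.67. DHCR7, which catalyses the last step of cholesterol synthesis, fell from 294.1 ± 14.6 TPM in WT to 94.7 ± 26.1 in T3-17, with 222.4 ± 12.9 in T3-8 (between clones -1.25; limma adjusted p = 0.00197). SLC13A3 and ZFPM2 fell by 1.29 and 1.23, with differences between clones of -1.45 and -1.49. CNTF fell by 1.30, but 33.4% of its exon length overlaps another annotated gene, so its value is uncertain.

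The clones were then compared with each other. CYBA, a subunit of the superoxide-producing NADPH oxidase (chromosome 16, 88643288 to 88651053), had 0.328 ± 0.223 TPM in T3-8, 22.0 ± 10.7 in WT and 96.4 ± 11.7 in T3-17, a difference between clones of 6.20 (SE 0.296; limma adjusted p = 4.43e-05). DUSP2, SFRP2, RUNX3 and RIOX1 were likewise higher in T3-17 than in T3-8, by 4.88, 4.70, 4.16 and 3.89. LCP1, an actin-bundling protein gene (chromosome 13, 46125922 to 46182177), had 71.7 ± 6.34 TPM in T3-8, 26.4 ± 1.75 in WT and 1.98 ± 0.675 in T3-17, a difference of -4.62 (SE 0.167; limma adjusted p = 1.41e-05). CTSF, a lysosomal cysteine protease gene, had 23.3 ± 0.108 TPM in T3-8, 11.5 ± 0.438 in WT and 0.0737 ± 0.0332 in T3-17 (difference -4.50). SPDYC, ZNF331 and ZNF804A were also lower in T3-17 than in T3-8, by -4.27, -4.058 and -4.003.

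Between the clones 2013 genes were higher and 2519 lower in T3-17 than in T3-8 (limma, Benjamini-Hochberg adjusted p under 0.05), with a median log2 fold change of -0.04 over all genes. Of the genes called in both clones against WT, 277 went in opposite directions. Of these, 124 were higher in T3-17 and lower in T3-8, and 153 the other way round. That these 277 were also called between the clones follows from their opposite signs and is no separate evidence. The count of 4532 calls between the clones became 1661 or 1887 without a T3-8 library and 7565 without T3-17 replicate 1.

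The fold changes of the clones correlated across genes, which are not independent replicates. Pearson's r was 0.505 and Spearman's rho 0.534 over the 13790 genes. Simulated unchanged clones that share the WT libraries had a mean r of 0.499, so r alone does not separate the data from shared controls. The covariance was 0.132, against 0.0109 in the simulations, a difference of 0.121, and 0.0921 after cyclic loess normalization.

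The difference from WT varied with how abundant a gene was. Genes at 2 to 5 TPM had a median log2 fold change of 0.54 in T3-8 and 0.51 in T3-17 (1139 genes). At 50 to 100 TPM the medians were 0.07 and 0.02 (2522 genes), and above 500 TPM they were -0.17 in both clones (209 genes). The summed TPM of the genes at 2 to 5 TPM was 1.66 times the WT sum in T3-8 and 1.65 times in T3-17, and over single clone and WT libraries the ratio lay between 1.58 and 1.71. Below that range, where the added 1 TPM shrinks fold changes, the summed TPM was 1.84 and 1.79 times the WT sum at 1 to 2 TPM and 2.41 and 2.20 times under 0.1 TPM. The 1000 most abundant genes took 47.5% of the TPM in both WT libraries, 43.9% and 44% in T3-8, and 43.9% and 46.2% in T3-17.

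**Figure D2:**
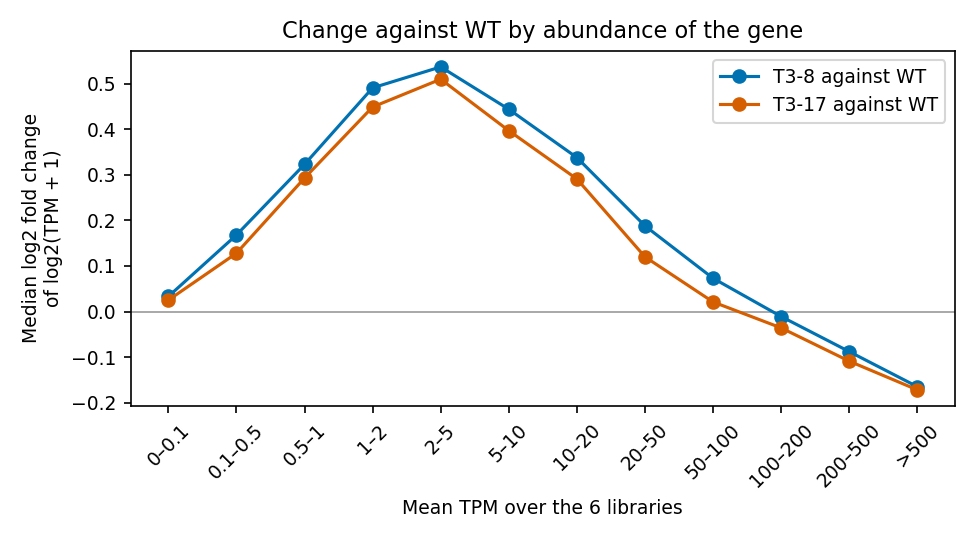
Median log2 fold change of log2(TPM + 1) against WT (vertical axis) for genes grouped by their mean TPM over the 6 libraries (horizontal axis), for T3-8 and T3-17; points are medians over the genes of a group. Both lines peak at 2 to 5 TPM, at 0.54 and 0.51, and lie below 0 above 100 TPM; the added 1 TPM lowers the medians to the left of the peak.

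Most genes of the cytosolic heat shock list fell in both clones. The list also holds HSPD1 and HSPE1, which encode mitochondrial chaperones. Of the 17 measured chaperone genes of this list, 13 fell and 2 rose in T3-8, and 11 fell and 1 rose in T3-17; adjusted over the list alone, 14 fell and 2 rose in T3-8, and 13 fell and 1 rose in T3-17. HSPA8, the constitutive cytosolic chaperone, fell from 2322 ± 15.9 TPM in WT to 1391 ± 37.3 in T3-8 and 1378 ± 106 in T3-17, and its partner DNAJB1 from 315.2 ± 4.44 to 202.4 ± 4.9 and 187.3 ± 8.37. STIP1, which links chaperone machines, fell from 305.5 ± 4.99 to 212.8 ± 5.12 and 145.3 ± 4.62 TPM, while the small heat shock protein gene HSPB1 rose from 135.7 ± 13.2 to 257.7 ± 40.1 and 362.8 ± 2.63 TPM. HSPA1A and HSPA1B are near-identical copies that share reads, so their separate falls are uncertain. The list median relative to all genes was -0.71 in T3-8 (camera of limma, adjusted p = 6.01e-10) and -0.62 in T3-17 (adjusted p = 1.62e-07), with adjusted p = 0.137 and 0.176 with an estimated correlation.

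Genes of cholesterol synthesis and its sterol-regulated control also fell. Of 22 measured genes 11 fell and 2 rose in T3-8, and 16 fell and 2 rose in T3-17; adjusted over the list alone, 12 fell in T3-8 and 16 in T3-17, with 2 higher in each. HMGCS1, an early enzyme of the pathway, fell from 192.1 ± 1.55 TPM in WT to 104.7 ± 3.08 in T3-8 and 62.6 ± 3.67 in T3-17, and SQLE, the squalene epoxidase gene, from 422.2 ± 5.24 to 207.2 ± 8.64 and 247.9 ± 9.01. INSIG1, which encodes a sterol-dependent brake on the pathway, fell from 419.5 ± 10.6 to 243.2 ± 3.8 and 136.2 ± 12.9 TPM. TM7SF2, a sterol reductase gene, rose from 24.9 ± 0.98 to 53.3 ± 2.17 and 41.2 ± 3.33 TPM. The list median relative to all genes was -0.59 in T3-8 (camera of limma, adjusted p = 3.5e-07) and -0.74 in T3-17 (adjusted p = 2.38e-09), with adjusted p = 0.137 and 0.169 with an estimated correlation. Between the clones the list did not pass camera (adjusted p = 0.116), although 12 members were lower and 3 higher in T3-17 than in T3-8.

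Immediate early genes, which respond within minutes to growth signals and stress, rose in both clones. Of 26 measured genes 21 rose and 1 fell in T3-8, and 22 rose with no call lower in T3-17; adjusted over the list alone, 21 rose and 1 fell in T3-8, and 23 rose in T3-17. FOS rose from 51.5 ± 3.54 TPM in WT to 138.1 ± 1.66 in T3-8 and 162.5 ± 8.97 in T3-17, and its partner JUN from 342.6 ± 28.1 to 1024 ± 63.5 and 1002 ± 49. FOSB rose from 17.3 ± 0.107 to 55.99 ± 2.09 and 51.2 ± 0.452 TPM. DUSP2, a phosphatase gene that limits MAP kinase signalling, was the member that fell in T3-8, by 2.30, and it rose by 2.58 in T3-17. The list median relative to all genes was 0.71 in T3-8 (camera of limma, adjusted p = 0.000264) and 0.92 in T3-17 (adjusted p = 1e-05), with adjusted p = 0.341 and 0.204 with an estimated correlation.

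Interferon-stimulated genes rose in both clones, and the clones differed in which members rose most. Of 28 measured genes 19 rose in each clone and none was called lower; adjusted over the list alone, 19 rose and 1 fell in T3-8, and 21 rose in T3-17. IFIH1, a cytosolic sensor of double-stranded RNA, went from 0.597 ± 0.157 TPM in WT to 6.25 ± 0.494 in T3-8 and 2.34 ± 0.355 in T3-17, and IFIT1 from 6.70 ± 0.28 to 15.6 ± 0.951 and 15.3 ± 0.241. IFI6 rose from 12.8 ± 0.542 to 32.2 ± 4.17 and 80.7 ± 15.7 TPM, and UBE2L6, an ISG15-conjugating enzyme gene, from 7.17 ± 1.69 to 23.5 ± 0.91 and 44.4 ± 2.25. IFITM2 rose in T3-8 from 27.3 ± 3.95 to 126.7 ± 11.9 TPM, against 27.3 ± 6.95 in T3-17 (between clones -2.19; limma adjusted p = 0.000362). The list median relative to all genes was 0.67 in T3-8 (camera, adjusted p = 0.000264) and 0.70 in T3-17 (adjusted p = 0.000874), with adjusted p = 0.137 and 0.176 with an estimated correlation.

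Targets of ATF4, the transcription factor of the integrated stress response, differed between the clones. Of 31 measured genes 19 rose and 2 fell in T3-17, and 11 rose and 4 fell in T3-8; adjusted over the list alone, 21 rose and 3 fell in T3-17, and 12 rose and 5 fell in T3-8. PCK2, the mitochondrial phosphoenolpyruvate carboxykinase gene, rose in T3-17 from 56.1 ± 3.95 to 196.1 ± 39.9 TPM and had 47.8 ± 1.79 TPM in T3-8 (between clones 2.00; limma adjusted p = 0.000194). CHAC1, a glutathione-degrading enzyme gene, had 32.5 ± 2.19, 61.1 ± 1.14 and 95.8 ± 13.6 TPM in WT, T3-8 and T3-17, and DDIT4, an inhibitor of mTOR signalling, had 188.7 ± 6.1, 259 ± 9.82 and 412.4 ± 43.3. ATF5 fell in T3-8 from 93.1 ± 7.33 to 56.8 ± 2.94 TPM, with 99.7 ± 3.31 TPM in T3-17. The list median relative to all genes was 0.36 in T3-17 (camera of limma, adjusted p = 0.00249, and adjusted p = 0.204 with an estimated correlation). In T3-8 it was -0.04 (camera of limma, adjusted p = 0.802) and turned to 0.11 with cyclic loess normalization (adjusted p = 0.198). Between the clones it was 0.34 (camera of limma, adjusted p = 0.000377; adjusted p = 0.919 with an estimated correlation), with 17 members higher and 3 lower in T3-17, both over all genes and adjusted over the list alone.

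Targets of p53 and genes of the G2/M phase passed against WT in T3-17. Of 28 measured p53 targets 17 rose and 2 fell in T3-17, and 15 rose and 3 fell in T3-8; adjusted over the list alone the counts were 17 and 2, and 16 and 3. CDKN1A, the cell cycle inhibitor gene, rose from 112.1 ± 1.08 TPM in WT to 175.5 ± 6.06 in T3-8 and 282.1 ± 3.78 in T3-17, and GADD45A from 76 ± 2.84 to 153.9 ± 2.52 and 144.9 ± 13.4. BBC3, a pro-apoptotic gene, rose in T3-8 from 30.3 ± 0.413 to 56.6 ± 0.935 TPM and had 35.1 ± 0.62 TPM in T3-17. Of 29 measured G2/M genes 16 rose and 1 fell in T3-17, and 8 rose and 2 fell in T3-8; adjusted over the list alone the counts were 17 and 1, and 8 and 2. The mitotic kinesin gene KIF2C had 57.6 ± 0.923, 69.5 ± 3.4 and 126.9 ± 11.6 TPM in WT, T3-8 and T3-17, and passed in T3-17. The p53 list had camera adjusted p = 0.0209 in T3-17 (median 0.21 relative to all genes; adjusted p = 0.257 with an estimated correlation) and 0.226 in T3-8. The G2/M list had camera adjusted p = 0.0129 in T3-17 (median 0.12; adjusted p = 0.45 with an estimated correlation) and 0.624 in T3-8, where its median was 0.00 and its mean -0.06 (limma). Neither list passed between the clones (camera adjusted p = 0.739 and 0.116), so a difference between the clones is not shown.

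**Figure D3:**
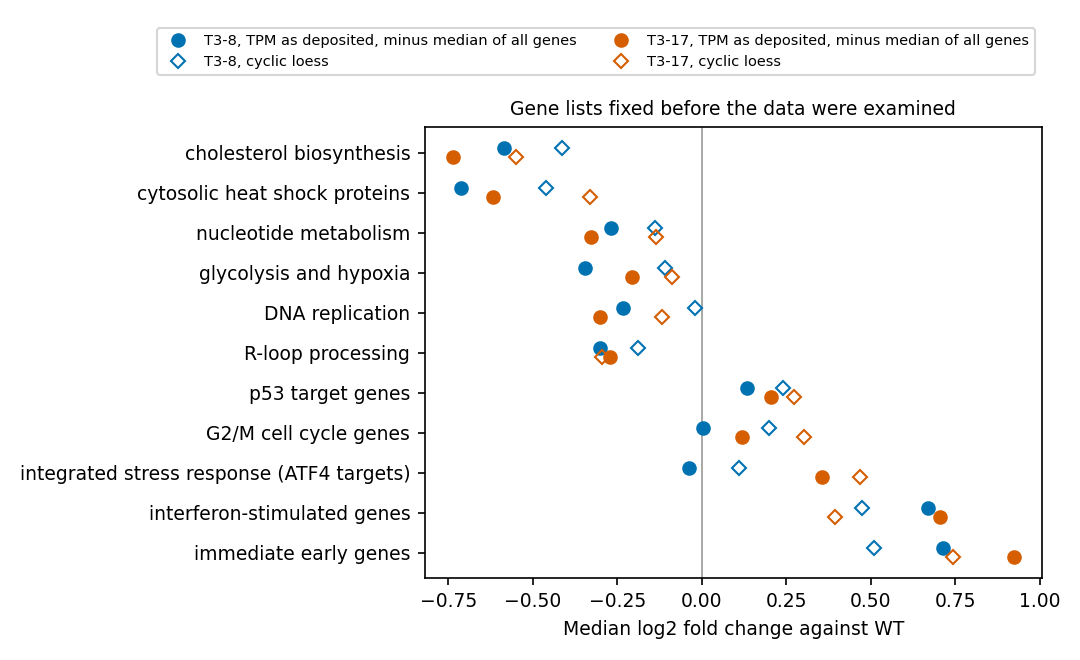
Median log2 fold change against WT (horizontal axis) of 11 gene lists fixed before the data were examined, in T3-8 and T3-17; filled points use TPM as deposited minus the median of all genes, and open diamonds use cyclic loess normalization. Immediate early genes lie at 0.71 and 0.92 and cholesterol synthesis genes at -0.59 and -0.74 with TPM as deposited.

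Lists closest to ribonucleotide removal and DNA topology held members that moved in both directions. Of 16 genes for ribonucleotide removal and hybrid nucleases, 3 rose and 4 fell in T3-8, and 4 rose and 6 fell in T3-17. The targeted gene RNASEH2A is in this list and is among its falls in both clones. Of all tested genes 41% were called in T3-8 and 43% in T3-17. Of 21 topoisomerase and topology genes, 4 rose and 3 fell in T3-8, and 4 of each were called in T3-17; the counts adjusted over the list alone were the same for both lists. TOP1, the topoisomerase that also cuts DNA at ribonucleotides, fell from 195.8 ± 14.1 TPM in WT to 104.7 ± 1 in T3-8 and 154.9 ± 11.2 in T3-17 (log2 fold changes -0.90 and -0.34; limma adjusted p = 0.000587 and 0.0192), and it was higher in T3-17 than in T3-8 (0.56, adjusted p = 0.00359). TOP1 lies on chromosome 20. Its 20 Mb window (40000001 to 60000000) had medians of -0.43 in T3-8 and 0.38 in T3-17 against T3-8, relative to all genes. The fall of TOP1 in T3-8 and its difference between the clones may thus in part be those of the segment. HMGB1, a DNA-bending protein gene, fell from 433.5 ± 8.66 to 289.9 ± 8.64 and 246.2 ± 2.14 TPM. TOP2A, the decatenating topoisomerase gene of dividing cells, had 234.3 ± 1.4, 299.6 ± 2.23 and 341.6 ± 16.7 TPM; its T3-8 call was lost with median-ratio scaling and without any 1 of the WT or T3-8 libraries. Neither list passed camera in a clone (limma, adjusted p = 0.0921 and 0.132 in T3-8, 0.0537 and 0.147 in T3-17).

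R-loop processing genes passed in both clones on a minority of members. Of 18 measured genes 2 rose and 4 fell in T3-8, and 1 rose and 5 fell in T3-17, the same counts as adjusted over the list alone. DDX21, an RNA helicase of the nucleolus, fell from 686.8 ± 8.59 TPM in WT to 465.2 ± 6.14 in T3-8 and 443.7 ± 46.2 in T3-17, and DHX9, a helicase that unwinds RNA:DNA hybrids, from 161.1 ± 6.28 to 111.7 ± 4.1 and 107.4 ± 13.6. The DHX9 call in T3-8 was lost without WT replicate 2 (limma adjusted p = 0.0593) or T3-8 replicate 1 (0.061). The list had camera adjusted p = 0.00515 in T3-8 and 0.00488 in T3-17 (relative medians -0.30 and -0.27; limma), with adjusted p = 0.525 and 0.45 with an estimated correlation. Of 30 checkpoint and repair genes 6 fell and no member was called higher in T3-17 (5 fell, adjusted over the list alone), and 4 rose and 3 fell in T3-8 by either count. NBN, of the MRN complex, fell in T3-17 from 69.7 ± 1.73 to 46.7 ± 3.75 TPM. NBN lies on chromosome 8, whose windows had medians from -0.39 to 0.21 in T3-17 relative to all genes. Its fall may thus in part be that of a segment. Whether members on shifted chromosomes carry the shift of the checkpoint and repair list was not tested. That list passed camera in T3-17 (relative median -0.20, adjusted p = 0.0129; adjusted p = 0.45 with an estimated correlation), lost the call without T3-17 replicate 2 (0.0787), and did not pass in T3-8 (adjusted p = 0.735) or between the clones (0.265).

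The replication and nucleotide lists had medians below that of all genes, with most members not called. Of 37 replication genes 6 rose and 7 fell in T3-8, and 5 rose and 7 fell in T3-17; adjusted over the list alone, 4 rose in T3-8 and the other counts were the same. The clamp gene PCNA had 601.8 ± 9.08, 496.8 ± 7.84 and 452.1 ± 38.4 TPM in WT, T3-8 and T3-17. It lies on chromosome 20, in a 20 Mb window with medians of -0.23 in T3-8 and -0.24 in T3-17 relative to all genes. Its lower values may thus in part be those of the segment. The licensing factor gene CDT1 rose from 177.7 ± 7.67 to 251.4 ± 5.86 and 240.1 ± 0.784. In T3-17 the PCNA call was lost without either WT library (limma adjusted p = 0.0511 and 0.0645) and the CDT1 call without WT replicate 2 (0.0531). Of 27 nucleotide metabolism genes 1 rose and 7 fell in T3-8, and 2 rose and 10 fell in T3-17, by both counts. DCTPP1, a pyrophosphatase gene that clears dCTP, fell from 651.6 ± 23.4 to 474.4 ± 4.58 and 389.2 ± 36.2 TPM, and RRM1, the large subunit of ribonucleotide reductase, fell in T3-17 from 295.2 ± 6.19 to 208.2 ± 7.23 with 281.4 ± 0.84 in T3-8. The replication list had relative medians of -0.23 and -0.30 (camera of limma, adjusted p = 0.00515 and 0.00917; adjusted p = 0.235 and 0.204 with an estimated correlation). The nucleotide list had -0.27 and -0.33 (adjusted p = 0.000122 and 0.000442; adjusted p = 0.137 and 0.176 with an estimated correlation, limma). The replication call in T3-17 was lost without T3-17 replicate 1 (0.0884). With cyclic loess normalization the replication medians were -0.02 and -0.12 (camera of limma, adjusted p = 0.506 and 0.386) and the nucleotide medians -0.14 and -0.14 (0.0681 and 0.076), and with quantile normalization the replication medians were -0.025 and -0.142 (0.478 and 0.293).

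Energy metabolism and matrix lists passed in both clones. Of 26 glycolysis and hypoxia genes 4 rose and 12 fell in T3-8 and 5 rose and 9 fell in T3-17, by both counts: LDHA, the lactate dehydrogenase gene, fell from 1225 ± 18.2 TPM to 687.9 ± 24.9 and 404.2 ± 77, while ENO2 rose from 21.6 ± 0.147 to 44.4 ± 1.96 and 58.1 ± 0.0863. Of 36 matrix genes 21 rose and 3 fell in T3-8 and 20 rose and 1 fell in T3-17 (22 and 3, and 20 and 1, adjusted over the list alone), with MMP2, a gelatinase gene, rising from 5.63 ± 0.148 to 18.9 ± 1.6 and 27.5 ± 3.15 TPM. Relative medians were -0.34 and -0.21 for glycolysis (camera of limma, adjusted p = 0.000477 and 0.0362; adjusted p = 0.137 and 0.257 with an estimated correlation) and 0.30 and 0.37 for matrix genes (adjusted p = 0.0391 and 0.0312; adjusted p = 0.689 and 0.652 with an estimated correlation, limma). Of 43 nuclear-encoded oxidative phosphorylation genes 3 rose and 6 fell in T3-8 and 4 rose and 8 fell in T3-17 (2 and 5, and 4 and 8, adjusted over the list alone); relative medians were -0.25 and -0.18 (camera of limma, adjusted p = 0.00515 and 0.0177; adjusted p = 0.654 and 0.617 with an estimated correlation). Without T3-17 replicate 1 the T3-17 calls of 3 of these ended, with adjusted p = 0.223 for glycolysis, 0.117 for matrix genes and 0.971 for oxidative phosphorylation. The oxidative phosphorylation median in T3-17 was -0.03 without T3-17 replicate 1 and -0.38 without T3-17 replicate 2. The T3-17 matrix call also ended without WT replicate 1 (0.0515).

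HOX, histone, ZNF and ribosomal protein lists passed in T3-8, and the chaperones of the endoplasmic reticulum in T3-17. HOX genes, which set position along the body axis, had 18 of 37 members higher and no call lower in T3-8, and 16 higher and 1 lower in T3-17, by both counts; HOXB6 rose from 97.47 ± 4.03 to 172.6 ± 6.71 and 153 ± 12.1 TPM. Their camera adjusted p was 0.0237 in T3-8 (relative median 0.08; adjusted p = 0.654 with an estimated correlation; 0.0665 without WT replicate 2) and 0.0875 in T3-17, and they did not pass between the clones (0.805, limma). The HOX median in T3-8 was 0.16 without WT replicate 1 and 0.14 without T3-8 replicate 1. Histone genes had 22 of 53 members higher and 1 lower in T3-8 and 19 higher and 2 lower in T3-17 (23 and 1, and 18 and 2, adjusted over the list alone), with H1-2, a linker histone gene, rising from 74.2 ± 2.08 to 210.8 ± 6.95 and 192.3 ± 7.11 TPM. Most histone messages lack a poly(A) tail, so this selection measures them poorly. The T3-8 calls of the histone list (camera adjusted p = 0.0481), of 413 ZNF genes (153 higher and 12 lower; 152 and 12 adjusted over the list alone; 0.0396) and of 75 ribosomal protein genes (10 higher and 6 lower; 9 and 3 adjusted over the list alone; 0.0481) had adjusted p = 0.525, 0.867 and 0.909 with an estimated correlation (limma). Relative medians were 0.45, 0.11 and -0.20 in that order. The histone call ended without WT replicate 1, T3-8 replicate 2 or either T3-17 library (adjusted p = 0.0732, 0.168, 0.0953 and 0.0945), the ZNF call without WT replicate 2 or either T3-8 library (0.0665, 0.0616 and 0.0573), and the ribosomal call with median-ratio scaling (0.105) and without WT replicate 1 or T3-8 replicate 1 (0.0732 and 0.0766, limma). The histone median was 0.30 without T3-8 replicate 2. With cyclic loess normalization the ribosomal median turned to 0.01. Of 20 endoplasmic reticulum chaperone genes 2 rose and 4 fell in T3-17 (4 fell and no call was higher, adjusted over the list alone), among them HYOU1 (log2 fold change -0.66) and MANF (-0.51). That list had camera adjusted p = 0.0132 (limma; relative median -0.28; adjusted p = 0.204 with an estimated correlation), and 0.0801 without T3-17 replicate 1.

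With cyclic loess normalization, chosen after seeing that fold changes vary with abundance, the heat shock, cholesterol, immediate early and interferon lists passed in both clones (camera of limma, adjusted p between 1.37e-06 and 0.00874). The HOX list in T3-8 and the stress response, p53, G2/M, R-loop and repair lists in T3-17 also passed. In T3-8 the R-loop, replication, nucleotide, glycolysis, oxidative phosphorylation, ribosomal, histone, matrix and ZNF calls ended, and in T3-17 the replication, nucleotide, chaperone, glycolysis, oxidative phosphorylation and matrix calls. The G2/M list in T3-8 and the HOX list in T3-17, which had not passed with TPM as deposited, passed with this normalization (camera of limma, adjusted p = 0.023 and 0.0241) and with quantile normalization (0.028 and 0.0335). With TPM as deposited these 2 lists had adjusted p = 0.909 and 0.709 with an estimated correlation (camera of limma), which was not run after this normalization. Medians in T3-8 and T3-17 were 0.47 and 0.39 for interferon-stimulated genes and -0.46 and -0.33 for heat shock genes with cyclic loess, and 0.42 and 0.38 for interferon-stimulated genes with quantile normalization. With cyclic loess they were -0.19 and -0.30 for R-loop genes, 0.16 for HOX genes in T3-8, and 0.30 for G2/M and -0.10 for repair genes in T3-17. Among the calls that ended they were -0.11 and -0.09 for glycolysis, -0.07 and -0.01 for oxidative phosphorylation and 0.33 and 0.18 for matrix genes, 0.25 for histone and -0.004 for ZNF genes in T3-8, and -0.08 for chaperones of the endoplasmic reticulum in T3-17.

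The rotation test fry of limma asks whether the genes of a list move 1 way on balance and compares them with no other genes, so the overall shift counts in it. It did not pass for some lists that passed camera: in T3-8 for R-loop, replication, oxidative phosphorylation and ribosomal genes (fry of limma, adjusted p = 0.165, 0.175, 0.694 and 0.694), and in T3-17 for R-loop, repair, replication, glycolysis and oxidative phosphorylation genes (0.0759, 0.195, 0.0789, 0.173 and 0.413). It passed for some that did not pass camera. In T3-8 these were p53 targets, G2/M genes, ATF4 targets, NF-kB targets, chaperones of the endoplasmic reticulum, neuronal genes and embryonic stem cell markers (fry of limma, adjusted p = 0.00639, 0.0464, 0.0143, 0.00285, 0.0234, 0.0464 and 0.0438). In T3-17 they were histone genes, NF-kB targets, HOX genes and epithelial carcinoma markers (fry of limma, adjusted p = 0.0168, 0.0133, 0.0308 and 0.0133). Between the clones they were cholesterol, chaperone, interferon, glycolysis and NF-kB genes (fry of limma, adjusted p = 0.00619, 0.00774, 0.0345, 0.0345 and 0.0337).

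Markers of other cell types did not pass camera in either clone. Embryonic stem cell, fibroblast, epithelial carcinoma and kidney epithelial lists had adjusted p of 0.624, 0.802, 0.942 and 0.8 in T3-8, and 0.699, 0.764, 0.0779 and 0.923 in T3-17 (camera of limma). Single members moved: the kidney developmental gene PAX2 rose by 1.11 in T3-8 and 1.01 in T3-17, and CDH1, the epithelial cadherin gene, had 2.99 ± 0.271, 9.13 ± 0.102 and 5.17 ± 0.657 TPM in WT, T3-8 and T3-17. The CDH1 call in T3-17 was lost with quantile normalization (0.11, limma adjusted p = 0.523), with cyclic loess (0.20, adjusted p = 0.227) and without WT replicate 2 (adjusted p = 0.078). Called members of the 4 lists in T3-8 numbered 3, 4, 2 and 3 higher and 0, 1, 0 and 1 lower (3, 4, 1 and 3, and 0, 1, 0 and 1, adjusted over the list alone), and in T3-17 2, 5, 5 and 3 higher and 1, 0, 0 and 1 lower (2, 5, 5 and 3, and 1, 0, 0 and 2, adjusted over the list alone). Only 4 of 19 CD4 T cell markers and 2 of 6 cancer-testis genes were kept, too few to test, and no gene of the mitochondrial genome was in the table. Lists for NF-kB targets, DNA methylation enzymes, nucleic acid sensing and neuronal genes did not pass camera (adjusted p = 0.116, 0.122, 0.799 and 0.8 in T3-8; 0.641, 0.0594, 0.804 and 0.699 in T3-17, limma), and neither did stress response and repair genes in T3-8.

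Within those lists, named members still changed. The maintenance methylation factor gene UHRF1 fell by 0.65 in T3-8 and 0.31 in T3-17, and the methyltransferase gene DNMT3A rose by 0.72 and 0.84. STING1, the adaptor of cytosolic DNA sensing, rose in T3-17 from 4.29 ± 0.744 to 15.2 ± 0.533 TPM and had 4.63 ± 1 TPM in T3-8 (between clones 1.54; limma adjusted p = 0.0011). NFKB2 rose in both clones, by 1.27 and 1.51. NEFM, a neurofilament gene, rose by 0.52 in T3-8 and fell by 0.91 in T3-17 (between clones -1.42; limma adjusted p = 6.22e-05). The UHRF1 call in T3-17 was lost without either WT library (limma adjusted p = 0.0889 and 0.109). Of the 12 sensing genes 2 rose in T3-8 and 4 rose and 2 fell in T3-17, by both counts.

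Clustered protocadherin genes, which encode neuronal adhesion molecules on chromosome 5 (140786290 to 141512981), gave largely 1 shared measurement for the gamma cluster. The 22 measured gamma cluster genes share their 3' exons, and the least-read gene held 98.1% to 99.6% of the reads of the median gene in each library. The median was 1221 and 1328 reads in WT, 674 and 710.5 in T3-8, and 2083.5 and 1667 in T3-17. The most-read gamma gene held more, with 2041 and 2262 reads in WT, 1061 and 1068 in T3-8, and 3683 and 3245 in T3-17. PCDHGC3 had 53.01 ± 0.651, 25.9 ± 0.796 and 74.0 ± 8.35 TPM in WT, T3-8 and T3-17 (limma adjusted p = 0.000633 in T3-8, 0.00895 in T3-17 and 0.000203 between the clones). PCDHGC3 was the only list member called in T3-17, where 22 were not called, so it does not stand for the shared signal there. Its T3-17 call was lost without either WT library (limma adjusted p = 0.0592 and 0.0691). Set tests of this list are left out, because its gamma members are for the most part not separate genes in these values. The only other member kept, the beta cluster gene PCDHB2, is a separate measurement and was called higher in T3-8 (limma, adjusted p under 0.05).

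Median fold changes differed between chromosomes, and the clones differed in which were low or high. In T3-8, genes on chromosomes 21, 20 and 14 had median log2 fold changes of -0.35, -0.30 and -0.30 relative to all genes (138, 379 and 466 genes), and those on chromosomes 6 and 22 had -0.15 and -0.13. Genes on chromosome 3 had 0.14. In T3-17, genes on chromosomes 11 and 13 had -0.40 and -0.29 (811 and 235 genes), those on chromosomes 7 and 20 had -0.20 and -0.17, and those on chromosomes 4 and 1 had 0.16 and 0.16. In T3-8 80.4% of the chromosome 21 genes and in T3-17 76.7% of the chromosome 11 genes lay below the median of all genes. Several genes named as lower in T3-17, among them RNASEH2C, DHCR7, LDHA, RRM1, STIP1 and CTSF, lie on chromosome 11. Their falls may in part be those of the chromosome. The same limit holds for changes of other named genes on shifted segments. Among them are TOP1 and PCNA on chromosome 20, NBN on chromosome 8 and RPL22 on chromosome 1. In windows of 20 Mb some of these chromosomes shifted in part. Chromosome 3 in T3-8 had 0.19 to 0.47 up to 120 Mb, -0.04 to 0.00 from 120 to 180 Mb and -0.22 beyond. Chromosome 1 in T3-17 had 0.24 to 0.55 up to 60 Mb and -0.20 to 0.01 beyond 140 Mb, and chromosome 20 in T3-17 ran from -0.35 to 0.09.

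With chromosomes as sets, 9 of the 22 passed camera in T3-8, 7 in T3-17 and 14 between the clones (limma, Benjamini-Hochberg over chromosomes). The adjusted p was 3.72e-10 for chromosome 21 and 2.02e-09 for chromosome 14 in T3-8, and 1.09e-15 for chromosome 11 in T3-17 (limma). With an estimated correlation none passed, with adjusted p = 0.105, 0.372 and 0.123 with an estimated correlation for these and 0.0536 as the lowest of any chromosome and comparison. The chromosome 20 call in T3-17 ended without T3-17 replicate 1. With cyclic loess normalization chromosome 4 lost its call in T3-8 and chromosome 16 gained one (camera of limma, adjusted p = 0.0677 and 0.0294). In T3-17 chromosomes 8, 18 and 22 gained calls with it (camera of limma, adjusted p = 0.034, 0.034 and 0.0452).

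**Figure D4:**
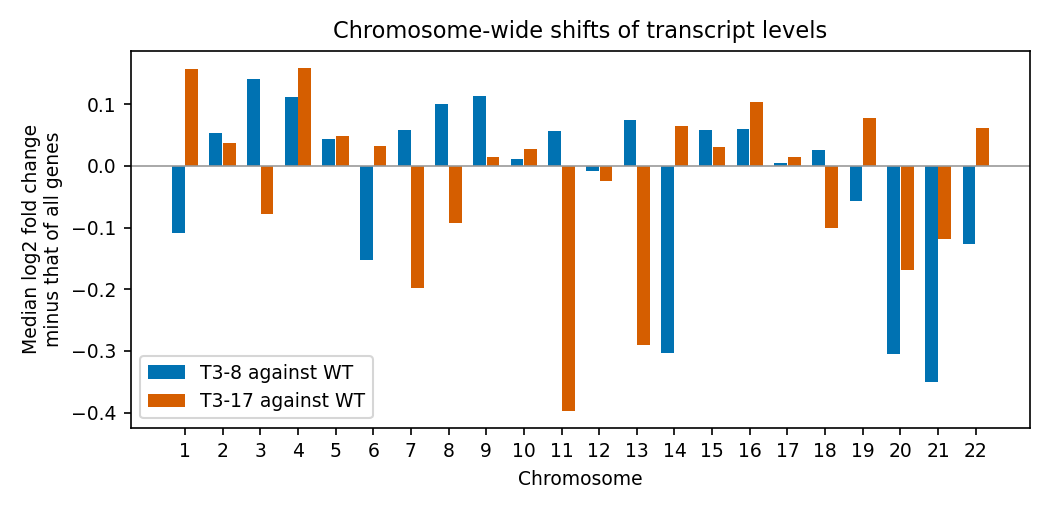
Median log2 fold change of the genes of each chromosome against WT, minus the median of all genes (vertical axis), for the 22 autosomes (horizontal axis) in T3-8 and T3-17. The lowest bars are chromosome 11 in T3-17, at -0.40, and chromosome 21 in T3-8, at -0.35.

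The DNA libraries served as a reference for how each fragmentation method covers the genome. Coverage from dsDNA Fragmentase (dsF), an enzyme mix that cuts with little sequence preference, was set against 3 combinations of restriction enzymes (RE1, RE2 and RE3), with 1 library per method, so no test between methods was possible. Mean depth per base was 7.59 for dsF, 10.4 for RE1, 12.3 for RE2 and 12.2 for RE3. Of 5760 bins of 500 kb on the autosomes 211 held no signal in any of the 4 libraries, and 5549 were used. The 10th to 90th percentile of the ratio to dsF ran from 0.964 to 1.05 for RE1, 0.958 to 1.06 for RE2 and 0.954 to 1.06 for RE3 over the 5528 bins at or above 0.5 times the dsF median.

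Among bins at or above 0.5 times the dsF median, few departed from dsF by 1.5-fold, and nearly all of these had a ratio below 1. RE1 had 12 such bins, all lower (0.217% of bins, exact binomial 95% interval 0.112% to 0.379%), RE2 had 53 lower and 1 higher (0.977%, 0.735% to 1.27%), and RE3 had 44 lower (0.796%, 0.579% to 1.07%). Bins with less dsF signal, where a high ratio is likelier, were left out, so this filter may have favoured ratios below 1. A low ratio can come from either library, so each was also set against its own median over bins, a check chosen after seeing the data. Of the 12 RE1 bins, 10 had dsF at 1.5 times its median or more and RE1 not below its own by 1.5-fold, with dsF at 3.21 and RE1 at 1.49 times the median as medians over the 12. Of the lower bins of RE2, 34 had RE2 low with dsF not high, 12 had dsF high with RE2 not low and 4 had both. For RE3 these counts were 30, 8 and 0. The bin on chromosome 3 from 93000001 to 93500000 had 0.171 times its dsF share with RE1 and 0.127 times with RE3, and the bin on chromosome 16 from 46000001 to 46500000 had 0.0379 times with RE2 and 0.311 times with RE1. The bin on chromosome 1 from 143000001 to 143500000 had 0.0694 times with RE2, and that on chromosome 4 from 49500001 to 50000000 had 0.291 times with RE3. The highest ratios were 1.56 with RE2 on chromosome 11 from 51000001 to 51500000, 1.43 with RE3 on the next bin of that chromosome, from 51500001 to 52000000, and 1.45 with RE1 on chromosome 22 from 18500001 to 19000000. Without chromosome ends and bins near empty bins, 6 bins remained off for RE1, 38 for RE2 and 28 for RE3.

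**Figure D5:**
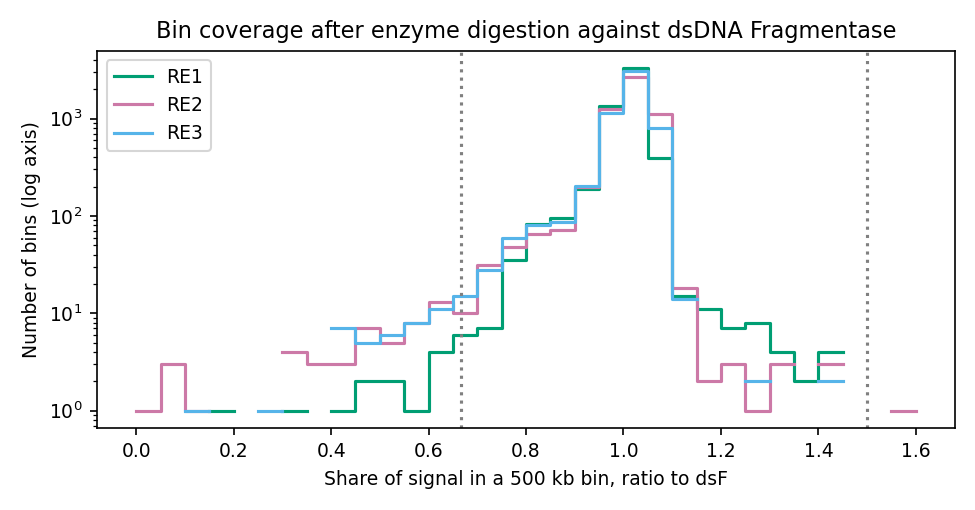
Number of 500 kb bins (log axis) by the ratio of their share of signal to that in dsF (horizontal axis), for RE1, RE2 and RE3, 1 library each; dotted lines mark a 1.5-fold difference and ratios with no bins are left blank. Most bins lie near a ratio of 1 and 53 bins of RE2 lie below the lower line.

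Correlation of bins with dsF was lowest for RE2. Spearman's rho with dsF over 5549 bins, which are not independent replicates, was 0.755 for RE1 (bootstrap 95% interval 0.74 to 0.771), 0.698 for RE3 (0.681 to 0.716) and 0.475 for RE2 (0.452 to 0.499). Pearson's r put RE3 first, with 0.83 for RE1, 0.866 for RE3 and 0.62 for RE2. The coefficient of variation over bins was 0.289 for dsF (0.157 to 0.425) and 0.152 for RE1 (0.115 to 0.195). It was 0.154 for RE2 (0.108 to 0.215) and 0.188 for RE3 (0.121 to 0.258), with intervals that overlap. The 10th to 90th percentile of bins relative to the library's median was narrowest for dsF, at 0.945 to 1.03. It ran from 0.911 to 1.05 for RE1, 0.93 to 1.04 for RE2 and 0.907 to 1.05 for RE3. The larger coefficient for dsF thus comes from bins outside that range. Median ratios per chromosome lay between 0.977, for RE1 on chromosome 19, and 1.04, for RE2 on chromosomes 16, 17 and 20. Intervals cover the spread over bins only, not that between libraries.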

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

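The tests of background reads, of 1 scaling factor per library and of reads shared by protocadherins were chosen after the result was seen. The others were chosen before, although cyclic loess, which 1 of these uses, was itself chosen after seeing the data. The patterns, and the chromosomes named in that test, were picked from these same data.

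The clones differed from each other. Called in opposite directions against WT were 277 genes. The largest differences, as T3-17 against T3-8, were 6.20 for the oxidase subunit gene CYBA, 4.88 for the phosphatase gene DUSP2, 4.70 for the Wnt modulator gene SFRP2, 4.16 for the transcription factor gene RUNX3 and 3.89 for the oxygenase gene RIOX1. On the other side were -4.62 for the actin-bundling gene LCP1, -4.50 for the protease gene CTSF, -4.27 for SPDYC, -4.058 for ZNF331 and -4.003 for ZNF804A. Targets of ATF4 had a median of 0.341 in T3-17 against T3-8 relative to all genes. These were singled out because 2 knockout clones of the same gene differ.

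Medians of whole chromosomes also differed between the clones, as T3-17 against T3-8 relative to all genes. Higher in T3-17 were chromosomes 14 (0.359), 21 (0.315), 1 (0.225), 22 (0.188), 6 (0.184), 20 (0.114) and 19 (0.1). Lower in T3-17 were chromosomes 11 (-0.484), 13 (-0.387), 7 (-0.245), 3 (-0.217), 8 (-0.154), 18 (-0.106) and 9 (-0.09). Windows of 20 Mb went both ways on some of these, from -0.80 to 0.45 on chromosome 3, -0.63 to 0.06 on chromosome 8, -0.25 to 0.74 on chromosome 1, -0.28 to 0.31 on chromosome 6 and -0.04 to 0.56 on chromosome 20. The calls of chromosomes 18 and 19 ended without T3-17 replicate 2, and that of chromosome 9 without T3-17 replicate 1.

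Genes of chromosome 11 in T3-17 and of chromosomes 14, 20 and 21 in T3-8 had medians below that of all genes. A trend with abundance as the whole cause is argued against by cyclic loess normalization, after which the smallest of the 4 shifts was 0.279 (chromosome 20, 95% interval -0.334 to -0.214). A different copy number of these chromosomes or long segments, which cell line clones can carry, stays open and was not tested. No DNA of these clones was analysed here, and whether such a change would follow from loss of RNase H2, from cloning or from another parent line was not tested.

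Genes of low abundance were higher in both clones than in WT. Reads spread over the genome are argued against by olfactory receptor genes, whose gain was at most 0.0184 of that of genes at 2 to 5 TPM. A single scaling factor per library is argued against by a shift at 2 to 5 TPM that exceeded that at 50 to 100 TPM by at least 0.449 in every pair of a clone and a WT library, and gene length by a difference of at least 0.438 in each of 4 groups of gene length. Loss of RNASEH2A, derivation of clones from single cells, and culture or library batch differ together between WT and the clones, and the parent line may differ as well, so these stay open and were not tested.

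The clustered protocadherins were singled out because their median differed between the clones, at 1.24 in T3-17 against T3-8. Reads shared between members fit the gamma cluster, where the least-read gene held at least 98.1% of the reads of the median gene. These genes are thus largely 1 measurement, although the most-read gene held more reads. The beta gene PCDHB2 is separate and was called higher in T3-8. Loss of a copy of the segment is argued against by the 46 other genes within 2 Mb, whose median in T3-8 relative to all genes was 0.101 (95% interval -0.024 to 0.183). Sharing of reads explains why members move together and not why the shared signal differs. A difference in promoter use or regulation between clones was not tested.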

How the results depend on the processing

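Cyclic loess, voom, quantile normalization of lists and of the correlation, and omission of the protocadherin list were chosen after seeing the data. RNASEH2A stayed lower in both clones in every setting. Of the genes, lists and chromosomes reported, 451 kept their direction and side of the threshold with a pseudocount of 0.1 and 2 lost a call, against 439 and 13 with median-ratio scaling. Calls lost were 27 with quantile normalization, with 2 reversed, 31 with cyclic loess, with 1 reversed, 33 (all list calls) with an estimated correlation, where no chromosome passed either, 41 and 53 without WT replicate 1 or 2, and 51 and 45 without T3-8 replicate 1 or 2.

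Where a value moved, the cause was not tested unless stated. T3-8 calls were 8596 with only the WT and T3-8 libraries, and T3-17 calls were 4777 with only the WT and T3-17 libraries. With all libraries they were 5648 and 5930, so which clone had more calls depends on the libraries that share the spread. Shared calls were 1861 with quantile normalization. Without 1 library, which leaves a group with 1 sample assumed to vary like the others, calls ran from 2461 to 8583 in T3-8, 3155 to 7973 in T3-17, 1661 to 7565 between the clones and 1329 to 4984 shared.

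Lists passing in T3-8 were 7 with quantile normalization and 7 with cyclic loess. With an estimated correlation 0 passed in T3-8, 0 in T3-17 and 0 between the clones. That setting also rests on the 3 residual degrees of freedom. In T3-8 the estimate was -0.0196 for cholesterol and -0.00725 for interferon genes, below the preset 0.01, and 0.191 for R-loop genes. Correlated members thus do not account for the loss of the cholesterol and interferon calls. Between the clones 1 passed without the protocadherin list, by construction, and 2 to 5 without 1 library. In T3-8 ribosomal protein genes turned to 0.007 with quantile normalization and 0.012 with cyclic loess, and ZNF genes to -0.01 with quantile normalization. In T3-17 oxidative phosphorylation genes ran from -0.378 to -0.028 without 1 library, reversed in test direction without T3-17 replicate 1. The correlation of the clones was 0.381 with quantile normalization and 0.416 with cyclic loess.

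Replicate numbers do not pair across groups (r = -0.0869, -0.0286 and 0.0492). With a replicate block calls were 5328 in T3-8, 5642 in T3-17, 4231 between the clones and 2825 shared.

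Bins off by 1.5-fold were 6 for RE1, 38 for RE2 and 28 for RE3 without chromosome ends and bins near empty bins; 4, 14 and 16 lay within 5 bins of an empty bin. Depth limits genes below 1 TPM, which rest on few reads.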

Other observations

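The genes named here were picked, and the correlations of ratios to dsF computed, after the data were seen.

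Single members of lists that did not differ between the clones went apart. COL2A1, the cartilage collagen gene, had 8.37 ± 0.928 TPM in WT (SD, n = 2), 0.305 ± 0.0372 in T3-8 and 13.1 ± 1.74 in T3-17, with a difference between clones of 3.43 (limma adjusted p = 3.75e-05). EYA1, a kidney developmental gene, had 4.95 ± 0.294, 12.9 ± 0.384 and 2.73 ± 0.786 TPM in the same order (-1.92; limma adjusted p = 0.000529), and its T3-17 call against WT ended without either WT library (limma adjusted p = 0.0562 and 0.0859). RPL22, a ribosomal protein gene, rose from 192.2 ± 0.832 TPM to 242.9 ± 7.84 in T3-8 and 494.8 ± 28.3 in T3-17. LAMB2, a laminin chain gene, rose alike in both clones, from 36.4 ± 0.27 to 82.3 ± 0.195 and 82.7 ± 8.23 TPM.

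The T3-17 replicates were less alike than those of the other groups. The SD of the log2 difference between replicates over genes was 0.301 in T3-17, 0.197 in WT and 0.183 in T3-8, and chi-square per degree of freedom was 35.1, 3.41 and 3.3. The first 2 principal components held 48.6% and 39.2% of the variance.

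Log2 ratios to dsF correlated between restriction digests, at 0.617 for RE1 and RE2, 0.568 for RE1 and RE3, and 0.691 for RE2 and RE3. These share dsF, so part of each value comes from the common denominator. Ranks of bins correlated directly between digests at 0.565 for RE1 and RE2, 0.748 for RE1 and RE3, and 0.63 for RE2 and RE3.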
